A study of Mus musculus with 18 samples.

How the data were processed

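Poly(A) RNA of mouse hippocampus and cerebral cortex was sequenced in 3 states of the tissue: fresh, snap-frozen by direct immersion in liquid nitrogen, and vitrified. Vitrification brings tissue to a glass without ice crystals by loading it with concentrated cryoprotectants before cooling. Per the labels' protocols, the vitrification solution held 28 wt% ethylene glycol, 22.3 wt% DMSO, 17.1 g sucrose and 32.6 wt% PBS, and was loaded in steps of 25%, 50%, 75% and 100% of 5 min each. The tissue was then cooled in liquid nitrogen, kept at -80 °C for 4 days, rewarmed at 37 °C and unloaded stepwise before extraction with TRIzol. Libraries were strand-specific (dUTP) and read on a DNBSEQ instrument, per the labels. There were 3 libraries in each of the 6 groups, 18 in all. The labels name neither the strain nor the animals, so p-values measure only the spread between these libraries, which may be technical.

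The deposited values are expected counts per gene: estimated counts that need not be whole numbers, which the authors gave in 1 table per tissue. Between 4.39% and 5.16% of the values of a library were not whole, the mark of a counter that divides reads between similar genes. Reads were aligned with HISAT2 2.0.4 to GRCm38.p6, per the submitters' processing notes; the counter, its strand setting and the gene annotation are not given in the sources used here. The values were rounded to whole numbers before testing. There were 18389 genes in the values of hippocampus and 18235 in those of cortex, all of which were also listed for hippocampus. Positions were found by symbol in GENCODE mouse release M21 (GRCm38), with a RefSeq table for the remainder, for 18196 symbols of the hippocampus table and 18042 of the cortex table. Of those in the hippocampus table, 98.8% were protein-coding, and 0 were mitochondrially encoded, so the share of mitochondrial transcripts was not analysed here. Genes with a value that is not whole in any library are described as sharing reads with a similar gene, and their changes are uncertain.

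The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to the 9 libraries of a tissue with a term for the group, after TMM scaling and the default expression filter of edgeR by group. It covered 14528 genes in hippocampus and 14470 in cortex. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. Standard errors (SE) of log2 fold changes were derived from the F statistic. The difference between tissues was tested as an interaction over all 18 libraries and 14827 genes. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated for each list; camera asks whether members of a list rank higher or lower than the other genes. Before the data were examined, 39 lists had been fixed, 24 of functions and RNA classes and 15 of markers of cell types or brain regions. Of these, 37 had at least 5 tested members; mitochondrially encoded genes and nuclear-retained long noncoding RNAs were too few to test. The lists share members: Slc1a2 and Slc1a3, for example, stand among both solute carriers and astrocyte markers, and Aqp4 among both osmotic stress genes and astrocyte markers.

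Also fixed before the data were examined were the groups, the tests, all alternatives but one kind, and the rule for named genes. For vitrified against fresh tissue the rule took the 8 largest rises and 8 largest falls among genes past the threshold, with a mean of at least 5 CPM (counts relative to the library size) in the higher group and no overlap between the libraries of both groups, and 12 fixed genes whatever their result. For the other comparisons and the interactions it took 5 each way, for overlaps the 5 with the smallest larger p, and from each list up to 4 changed members with the smallest p. Predicted genes were left out. Some genes that the rule takes are not reported here. Il1b, one of the fixed genes, was too low to be tested in either tissue.

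Where a gene had 0 counts in all libraries of a group, its fold was computed against 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio is given with its exact 95% binomial interval. These floors and intervals cover counting error only. In single libraries, 3 counts corresponded to 0.172 to 0.191 CPM. Overlaps of comparisons that share their fresh libraries were set beside 20 simulations of unchanged groups and beside the overlap of independent lists.

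Alternatives were median-of-ratios (RLE) factors, library totals without composition factors, other filters on low counts (none, or at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, only the libraries of the compared groups, a replicate block, offsets removing each library's trend on GC content and transcript length (lowess span 0.3), fry in place of camera, a log2 fold change over 1, and each library left out in turn. Fits with an assumed biological coefficient of variation of 10% and 20% were added after seeing the data, because the replicates proved so alike. Counting pairs of libraries within sampling noise as 1 was planned and not run: in all 18 pairs of replicates the spread exceeded the sampling noise, with a largest chi-square p of 3.7e-68 and a chi-square of 1.22 to 3.89 per degree of freedom (1.22 to 1.60 without snap_frozen replicate 3 of cortex). The procedure was tested on simulated data in 8 runs of 200 planted genes each, of 14183 to 14338 genes drawn at the observed means and depths. It recovered 82% to 97% of the genes planted at a log2 change of 1 and 75% to 86.9% of those planted at 0.5, with 6 to 18 false calls per run. Planted genes were few, went up as often as down, and had the spread estimated from these same libraries. These rates therefore do not carry over to comparisons in which many genes pass. Nor do they test whether the small spread between libraries is technical.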

Results

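Gene expression was measured in mouse hippocampus and cerebral cortex that were extracted fresh, after snap freezing, or after vitrification, cryoprotectant unloading and rewarming. Each tissue and state had 3 libraries. Total counts ranged from 15725356 to 17480302 per library. In hippocampus they were 16908624 to 17022164 in fresh, 16632142 to 16696505 in snap-frozen and 15808819 to 15987074 in vitrified tissue, and in cortex 16904072 to 17085727, 17289466 to 17480302 and 15725356 to 16066001. Between 16312 and 16641 genes had counts above 0, and the 10 most abundant genes took 2.77% to 3.10% of the counts. Libraries of one group were alike: the common coefficient of variation beyond sampling noise was 1.69% in hippocampus and 2.71% in cortex, and the lowest correlation of log2 CPM between replicates was 0.993. Small differences therefore passed the test. Replicate 3 of snap-frozen cortex stood apart from its group, at -19.4 on the second principal component against -11.1 for both others. The first principal component set snap-frozen hippocampus apart from the other states (66.5% of the variance) and, in cortex, vitrified tissue (47.2%).

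The first question was which transcripts differed between vitrified and fresh hippocampus. Transcripts of astrocytes were lower in vitrified tissue. Aqp4, the water channel of astrocyte endfeet (ENSMUSG00000024411.10, GRCm38 chromosome 18, 15389496 to 15410982, minus strand), was at 146.9 ± 1.68 CPM (mean ± SD, n = 3) in fresh and 46.9 ± 1.11 in vitrified hippocampus, a log2 fold change of -1.65 ± 0.03 (SE, adjusted p = 4.3e-37). The glutamate transporters Slc1a2 (-1.52 ± 0.02) and Slc1a3 (-1.56 ± 0.02) and the intermediate filament Gfap (-1.58 ± 0.03) fell as far. All 16 tested astrocyte markers fell, with a median of -1.41 (camera, adjusted p = 8.8e-148). Cldn5, a tight junction protein of brain endothelium, rose from 16.2 ± 0.248 to 29.1 ± 1.67 CPM (log2 0.85 ± 0.07, adjusted p = 3.3e-15).

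Markers of other cell types moved both ways in vitrified hippocampus. All 12 ependymal markers fell (median -1.76, adjusted p = 0.00138), among them Foxj1, the regulator of motile cilia (-1.64 ± 0.12). Of 17 microglial markers, 14 fell and 0 rose (median -0.61, adjusted p = 5.7e-10), with Csf1r at -0.76 ± 0.04 and Cx3cr1 at -0.74 ± 0.05. All 16 endothelial markers rose (median 0.65, adjusted p = 5.4e-14), for example the transporter Slco1a4 (1.33 ± 0.05) and the VEGF receptor Flt1 (0.98 ± 0.05). Of 7 blood cell markers, 6 rose and 1 fell (median 0.89, adjusted p = 2.7e-05), with the haemoglobin gene Hba-a1 at 1.14 ± 0.06; it and 3 others of the 7 share reads with similar genes, which makes this list uncertain in every comparison. These 5 cell type calls, astrocytes included, held with an estimated correlation, with adjusted p from 6.6e-05 to 0.0378. Oligodendrocyte markers also ranked lower (11 of 16 fell and 2 rose, median -0.28, adjusted p = 5.8e-05), but with adjusted p = 0.0815 with an estimated correlation. Among them Trf fell (-0.45 ± 0.02) while Mbp, at 3553 ± 7.66 against 3070 ± 71.2 CPM, rose by 0.21 ± 0.02. Of 13 markers of oligodendrocyte precursors 8 fell (median -0.21, adjusted p = 0.0458, and 0.124 with an estimated correlation). This call was lost without fresh replicate 2 (adjusted p = 0.0565), without vitrified replicate 1 (0.0513) or with a replicate block (0.0502).

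Among functional groups in vitrified hippocampus, the scaffolds of the postsynaptic density fell: 17 of 27 were lower and 4 higher (median -0.20, adjusted p = 5.4e-14, and 0.00224 with an estimated correlation). Shank3 (-0.97 ± 0.03), Shank1 (-0.78 ± 0.03), Dlgap3 (-0.71 ± 0.02) and the kinase Camk2a (-0.58 ± 0.02) led this group. Of 20 genes of the unfolded protein and integrated stress response, 12 fell and 0 rose (median -0.18, adjusted p = 7.6e-06), with the chaperone Hspa5 going from 430 ± 7.61 to 268 ± 5.55 CPM (-0.68 ± 0.02). Of 17 oxidative stress genes 12 fell and 0 rose (median -0.29, adjusted p = 0.0015), including the cystine transporter Slc7a11 (-1.15 ± 0.05) and the metallothionein Mt1 (-0.63 ± 0.04). Astrocyte markers fell in the same comparison, and the oxidative stress genes were not separated from them. Of 23 cholesterol synthesis genes 15 fell, or 16 adjusted over the list alone (median -0.19, adjusted p = 0.00133), for example Hmgcs1 (-0.43 ± 0.03) and Idi1, which shares reads with a similar gene (-0.66 ± 0.05). With an estimated correlation these 3 lists kept adjusted p of 0.0237, 0.0378 and 0.0374. Heat shock genes also ranked lower (13 of 21 fell, 1 rose, median -0.15, adjusted p = 0.0151). So did replication-dependent histones, of which 6 share reads (9 of 10 fell, 10 adjusted over the list alone, median -0.86, adjusted p = 0.0027) and the cytoskeleton (9 of 30 rose, 11 fell, 12 adjusted over the list alone, median -0.03, adjusted p = 0.0177). All 3 had adjusted p = 0.0815 with an estimated correlation. Of 57 histone genes listed for hippocampus, only 10 could be tested. Glycolytic enzymes ranked lower (3 of 17 rose, 6 fell, 7 adjusted over the list alone, median -0.02, adjusted p = 0.0146, and 0.167 with an estimated correlation); Aldoc, which astrocytes express, fell by 1.38 ± 0.02.

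The title of the series points to membrane proteins. Apart from cholesterol synthesis, the lists tied to membranes did not pass the test in vitrified hippocampus. Of 141 voltage-gated and leak ion channels 44 rose and 37 fell (45 and 38 adjusted over the list alone, median 0.04, adjusted p = 0.72), the largest of the falls among its leading members being those of Kcnj10 (-1.58 ± 0.03) and Kcnj16 (-1.71 ± 0.08), potassium channels of glia. Ionotropic receptors (11 of 56 rose and 12 fell, adjusted p = 0.991) and G protein-coupled receptors (25 of 158 rose and 50 fell, or 24 and 50 adjusted over the list alone, median -0.06, adjusted p = 0.204) had mixed members. So had solute carriers (76 of 280 rose and 78 fell, or 78 and 82, median 0.03, adjusted p = 0.47). The same held for cell adhesion molecules (25 of 145 rose and 49 fell, median -0.07, adjusted p = 0.174) and synaptic vesicle genes (18 of 45 rose and 15 fell, median 0.05, adjusted p = 0.286). The respiratory chain had 39 of 79 members lower and 3 higher (40 and 3 adjusted over the list alone, median -0.09, adjusted p = 0.0695), and passed without fresh replicate 1 (0.0464) or vitrified replicate 1 (0.0135). Cytosolic ribosomal proteins (33 of 83 fell, 1 rose, median -0.06, adjusted p = 0.157) passed without vitrified replicate 1 (0.0158). Proteasome subunits (10 of 37 rose, 4 fell, or 3 adjusted over the list alone, adjusted p = 0.158) and aminoacyl-tRNA synthetases (4 of 18 rose, 3 fell, 0.735) did not pass.

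Markers of neurons and brain regions and immediate early genes did not pass in this comparison. Slc17a7, the vesicular glutamate transporter of excitatory neurons, was at 1748 ± 7.32 CPM in vitrified and 1749 ± 7.17 in fresh hippocampus (log2 -0.00 ± 0.02, adjusted p = 0.97), and Gad1, which makes GABA, at 351 ± 10.3 and 353 ± 7.92 (-0.01 ± 0.02, 0.74). Excitatory markers (6 of 15 rose, 3 fell, adjusted p = 0.991), inhibitory markers (1 of 16 rose, 6 fell, 0.276) and markers of the dentate gyrus and hippocampal fields (7 of 15 rose, 3 fell, 0.79) were mixed. Markers of striatum (3 of 14 rose, 3 fell, 0.991) and thalamus (4 of 14 rose, 5 fell, 0.991) did not pass. Neither did those of choroid plexus (1 of 11 rose, 5 fell, median -0.41, 0.47), pericytes and smooth muscle (4 of 13 rose, 1 fell, 0.47) and meningeal fibroblasts (6 of 14 rose, 1 fell, median 0.23, 0.229). Immediate early genes (7 of 32 rose, 11 fell, adjusted p = 0.632) included Fos at -0.94 ± 0.12 and Klf2, a flow-responsive factor of endothelium, at 1.50 ± 0.11. The lists of osmotic stress (5 of 14 rose, 5 fell, 0.117), inflammation (4 of 12 rose, 4 fell, 0.991) and apoptosis (7 of 19 rose, 4 fell, 0.991) did not pass. Of single stress genes, Hspa1a did not pass (0.14 ± 0.07, adjusted p = 0.079; it shares reads with a similar gene), the osmolyte transporter Slc5a3 fell by 0.40 ± 0.05, and Hmox1 fell by 0.43 ± 0.13 (adjusted p = 0.0065, but 0.0966 without vitrified replicate 1). Ttr rose by 0.56 ± 0.12. Median, mean and camera direction differed in sign for 6 of the 37 lists, 0 of which passed.

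Among genes above 5 CPM, the largest rises in vitrified hippocampus included the endothelial transcription factor Sox17, at 10.4 ± 0.191 against 2.58 ± 0.476 CPM (2.01 ± 0.13), Gata2 (1.76 ± 0.17), xanthine dehydrogenase Xdh (1.64 ± 0.15), Pear1 (1.58 ± 0.16), Pla2g4e (1.56 ± 0.12) and Acer2 (1.55 ± 0.15). Gdf1 had the highest fold change (2.65 ± 0.29), but shares reads with a similar gene and ranged widely (44 ± 21.6 CPM). The largest falls were of the iron oxidase Heph, from 10.6 ± 0.726 to 1.87 ± 0.203 CPM (-2.50 ± 0.14), Aass (-2.13 ± 0.17), Klhdc7a (-1.98 ± 0.10), Ak7 (-1.95 ± 0.17), Thbs4 (-1.94 ± 0.08), Papss2 (-1.86 ± 0.08), Cyp2j9 (-1.80 ± 0.08) and Ccdc153 (-1.80 ± 0.18). In all, 550 of 14528 genes changed by over 1 on the log2 scale, 167 upwards and 383 downwards, and 7135 passed the test at any size (3463 rose, 3672 fell, median absolute log2 change 0.28). For 54.6% of genes the libraries of both groups did not overlap, where chance gives 10%. With library totals in place of composition factors, which shifts the median of all genes by 0.05, 4806 rose and 2835 fell. An assumed biological variation of 10% left 2481 genes and one of 20% left 673.

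**Figure D1:**
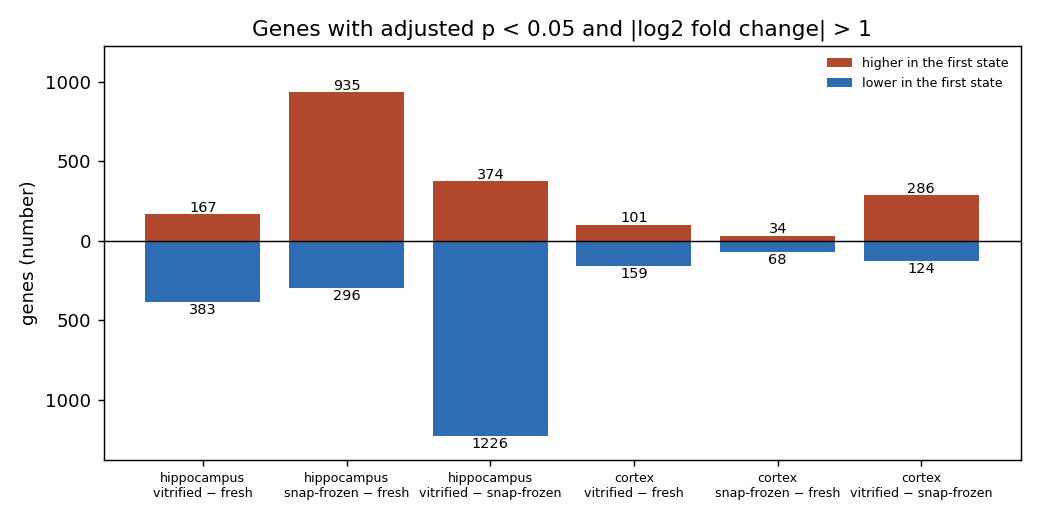
Genes that passed the test (adjusted p below 0.05) with an absolute log2 fold change over 1, for each tissue and comparison. Bars above 0 count genes higher in the first-named state and bars below 0 those lower in it. Each group had 3 libraries.

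Vitrified cortex was lower than fresh cortex in transcripts of the choroid plexus, the meninges and astrocytes. Ttr, which the choroid plexus secretes as a thyroxine carrier (ENSMUSG00000061808.4, GRCm38 chromosome 18, 20665280 to 20674321, plus strand), was at 330 ± 43.9 CPM (n = 3) in fresh and 1.29 ± 0.315 in vitrified cortex, a log2 fold change of -7.99 ± 0.12 (adjusted p = 8.5e-29). All 14 choroid plexus markers fell (median -3.08, adjusted p = 2.4e-38), among them Kl (-2.51 ± 0.13) and Clic6 (-1.65 ± 0.12). Of 14 meningeal and perivascular fibroblast markers 13 fell (median -1.16, adjusted p = 3.5e-18), with Col1a2 at -1.59 ± 0.07 and Igf2 at -1.13 ± 0.05. All 16 astrocyte markers fell (median -0.85, adjusted p = 5.4e-86), Aqp4 going from 151 ± 3.34 to 62.7 ± 2.79 CPM (-1.27 ± 0.04), Gfap by -1.32 ± 0.04 and Slc1a3 by -0.97 ± 0.03. These 3 calls held with an estimated correlation (adjusted p 0.000850 to 0.00205). Whether the samples held unlike amounts of choroid plexus and meninges by dissection was not tested.

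Of 32 immediate early genes, which neuronal activity induces, 20 fell and 3 rose in vitrified cortex (median -0.30, adjusted p = 1.5e-10, and 0.00237 with an estimated correlation). Arc fell by 1.57 ± 0.04, Fos by 1.39 ± 0.08, from 22.1 ± 0.564 to 8.40 ± 0.615 CPM, and Egr1 by 0.71 ± 0.04. Genes of the unfolded protein and integrated stress response fell (12 of 20, 0 rose, median -0.21, adjusted p = 1.7e-07, and 0.036 with an estimated correlation), with Hspa5 at -0.64 ± 0.03 and Pdia4 at -0.60 ± 0.05. Oxidative stress genes fell as well (11 of 17, 0 rose, median -0.20, adjusted p = 3.4e-05, and 0.0215 with an estimated correlation), Slc7a11 by 1.10 ± 0.05. They were not separated from astrocyte markers, which fell too. Postsynaptic scaffolds ranked lower (16 of 27 fell, 5 rose, median -0.17, adjusted p = 3.9e-11), Shank3 by -0.77 ± 0.03 and Homer1 by -0.70 ± 0.03, with adjusted p = 0.259 with an estimated correlation. Endothelial markers ranked higher (13 of 16 rose, median 0.31, adjusted p = 6.5e-06, and 0.161 with an estimated correlation), Slco1a4 by 0.93 ± 0.07 and Cldn5 by 0.44 ± 0.07. Blood markers (6 of 7 rose, median 0.33, adjusted p = 0.0353) and ependymal markers (6 of 10 fell, 7 adjusted over the list alone, median -0.84, adjusted p = 0.0409) both had adjusted p = 0.361 with an estimated correlation. The ependymal call was lost without vitrified replicate 2 (0.0505) or 3 (0.0650), with RLE factors (0.0641) and with GC and length offsets (0.109).

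Heat shock genes ranked lower in vitrified cortex (10 of 21 fell, median -0.12, adjusted p = 0.00676, and 0.16 with an estimated correlation), as did histones, of which 4 share reads (6 of 9 fell, 8 adjusted over the list alone, median -0.52, adjusted p = 0.0179, and 0.139 with an estimated correlation). Osmotic stress genes were mixed and ranked lower (4 of 14 rose, or 5 adjusted over the list alone, 7 fell, median -0.08, adjusted p = 0.0452, and 0.183 with an estimated correlation). The osmotic list, in which Aqp4 fell while the taurine transporter Slc6a6 (0.33 ± 0.04) and its regulator Nfat5 (0.36 ± 0.04) rose, was lost without vitrified replicate 1 (0.0779), and with GC and length offsets it and the histones stood at 0.0531. Of 54 histone genes listed for cortex, only 9 could be tested. Lists of channels, receptors, transporters, adhesion molecules and synaptic vesicles did not pass. Of 143 ion channels 45 rose and 31 fell (47 and 33 adjusted over the list alone, adjusted p = 0.702). Ionotropic receptors (14 of 49 rose, 2 fell, 0.419) and G protein-coupled receptors (27 of 160 rose, 38 fell, 0.279) had members that moved either way. The same held for solute carriers (61 of 277 rose, 62 fell, or 63 and 65, 0.138), adhesion molecules (23 of 144 rose, 30 fell, 0.463) and synaptic vesicle genes (16 of 45 rose, 10 fell, 0.439). Slc17a7 (-0.01 ± 0.02, adjusted p = 0.88), Gad1 (0.03 ± 0.03, 0.40), Hspa1a (0.08 ± 0.08, 0.46) and Hmox1 (-0.06 ± 0.13, 0.77) did not pass either, while Mbp rose by 0.25 ± 0.02 and Slc5a3 fell by 0.25 ± 0.07. The respiratory chain (1 of 79 rose, 6 fell, or 0 and 5 adjusted over the list alone, 0.279), ribosomal proteins (4 of 83 fell, 2 adjusted over the list alone, 0.732) and proteasome subunits (7 of 37 rose, 1 fell, or 2 and 0, 0.439) moved little. Glycolytic enzymes (3 of 17 rose, 3 fell, or 2 adjusted over the list alone, 0.419), aminoacyl-tRNA synthetases (3 of 18 rose, 3 fell, or 0, 0.785) and the cytoskeleton (8 of 30 rose, 8 fell, 0.279) did not pass. Neither did cholesterol synthesis (4 of 24 rose, 8 fell, 0.279), inflammation (2 of 11 rose, 2 fell, 0.547) and apoptosis (6 of 19 rose, or 7 adjusted over the list alone, 4 fell, 0.793). Among cell types and regions, microglial markers (1 of 17 rose, 9 fell, median -0.12, 0.104) and oligodendrocyte markers (6 of 16 rose, 3 fell, or 4 adjusted over the list alone, median 0.04, 0.396) did not pass. The same was true of excitatory (7 of 15 rose, 2 fell, or 3, 0.562) and inhibitory neurons (4 of 16 rose, 3 fell, 0.714), of oligodendrocyte precursors (3 of 13 rose, 4 fell, 0.547) and of pericytes (2 of 13 rose, 2 fell, 0.793). Regional markers did not pass either, whether of dentate gyrus (4 of 14 rose, 3 fell, 0.88), striatum (2 of 15 rose, 6 fell, or 7, 0.348) or thalamus (2 of 14 rose, 3 fell, 0.44). Median, mean and camera direction differed in sign for 8 of the 37 lists, ion channels and adhesion molecules among them, of which 0 passed.

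The largest rises in vitrified cortex above 5 CPM were of Galnt15 (1.80 ± 0.18), Xdh (1.71 ± 0.16), Pla2g4e (1.43 ± 0.09) and the collagens Col24a1 (1.39 ± 0.09) and Col6a4 (1.36 ± 0.13). The imprinted gene Ndn rose to 242 ± 5.29 from 93.6 ± 2.37 CPM (1.37 ± 0.03), beside the spindle checkpoint kinase Bub1b (1.29 ± 0.17) and Hmcn1 (1.26 ± 0.15). After Ttr, the largest falls were of Kcnj13, a potassium channel of choroid plexus (-3.09 ± 0.26), the macrophage mannose receptor Mrc1 (-2.83 ± 0.20), Kl, Itih2 (-2.04 ± 0.18), Myoc (-1.94 ± 0.07), Heph (-1.83 ± 0.13) and Prg4 (-1.74 ± 0.16). In all, 260 of 14470 genes changed by over 1 on the log2 scale, 101 upwards and 159 downwards, and 5855 passed at any size (3353 rose, 2502 fell, median absolute log2 change 0.28). The excess of rises depended on the scaling and filter: 2966 rose and 2877 fell with RLE factors, 3048 and 3135 with GC and length offsets, 2903 and 2996 without a filter, 2210 and 2297 with DESeq2, and 3232 and 3268 with only the libraries of both groups, but 3716 and 2257 with library totals. Libraries did not overlap for 52.5% of genes, against 10% by chance. An assumed variation of 10% left 1929 genes and one of 20% left 283.

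**Figure D2:**
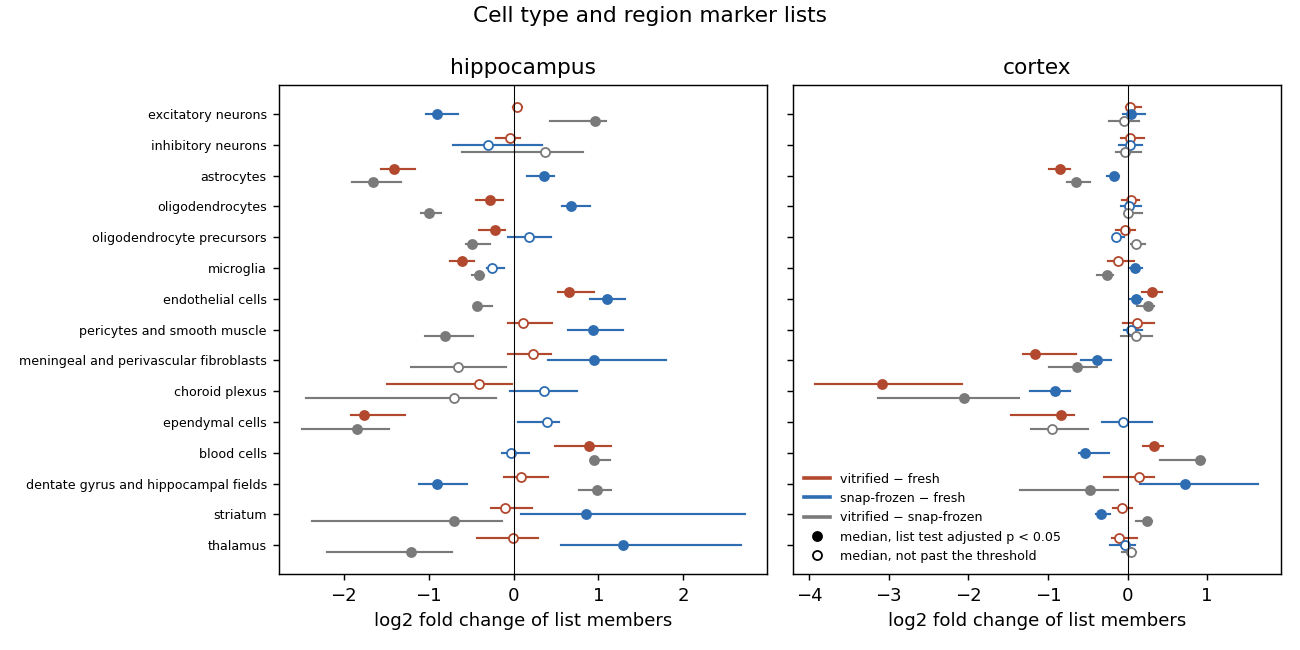
Log2 fold changes of markers of cell types and brain regions in hippocampus (left) and cortex (right). Points are list medians, and lines span the quartiles of the members. Colours are comparisons. Filled points passed the camera test at a preset correlation (adjusted p below 0.05) and open points did not.

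The changes on vitrification were compared between tissues. Of 14218 genes tested in both, 4117 changed in the same direction, 2209 upwards and 1908 downwards, and 163 in opposite directions; independent lists would share 1433 in the same direction. Of the 4117, 89 changed by over 1 in both tissues, 27 upwards and 62 downwards. Those with the strongest evidence in both were Ndn (1.43 in hippocampus and 1.37 in cortex), Gfap (-1.58 and -1.32), Fam107a (-1.40 and -1.03), Snhg11 (0.80 and 1.00) and Slc1a3 (-1.56 and -0.97). Ndn also rose after snap freezing (1.63 and 1.53), so its rise was not particular to vitrification. Across genes, which are not independent replicates, the log2 fold changes of the tissues had a Pearson r of 0.61 and a covariance of 0.0808. The labels do not say whether both tissues came from the same animals. If they did, a difference between the animals of the states would appear in both tissues, and their lists would not be independent.

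Snap-frozen hippocampus was compared with fresh hippocampus to separate freezing without cryoprotectant from vitrification. It was higher in transcripts of other brain regions and lower in those of hippocampal neurons. The thalamic and subcortical genes Slc17a6, the vesicular glutamate transporter of subcortical neurons (4.50 ± 0.05), and Tcf7l2 (4.95 ± 0.07) were among 12 of 14 thalamic markers that rose, 0 falling (median 1.29, adjusted p = 8.1e-21). Of 14 striatal markers 8 rose, or 9 adjusted over the list alone, and 1 fell (median 0.85, adjusted p = 7.9e-07), with the dopamine receptor Drd2 at 2.88 ± 0.11. Of 15 markers of the dentate gyrus and hippocampal fields 14 fell (median -0.90, adjusted p = 2.5e-13), Fibcd1 by 1.52 ± 0.03 and Zbtb20 by 1.51 ± 0.05. Of 15 excitatory markers 13 fell and 2 rose (median -0.90, adjusted p = 2.7e-20), Slc17a7 by 1.27 ± 0.02. The adjusted p of these lists were 0.00171, 0.0234, 0.00262 and 0.000983 with an estimated correlation.

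Transcription factors of thalamus, hypothalamus and midbrain led the rises. Barhl1 (ENSMUSG00000026805.14, GRCm38 chromosome 2, 28907679 to 28916668, minus strand) had 0 counts in the 3 fresh libraries and 847 in the 3 snap-frozen ones, at least 288-fold higher (adjusted p = 4.6e-29). Tfap2d had 1 count against 1981, a ratio of 2018 with an interval of 362 to 79766, Shox2 2 against 2109, a ratio of 1074 (297 to 8878), and Gata3 1 against 395, a ratio of 402 (71.8 to 15937). Tfap2b rose by 7.89 ± 0.22. The largest falls were of Dio3, which inactivates thyroid hormone (-4.65 ± 0.24), Krt2 (-2.96 ± 0.17), Cpne7, from 404 ± 3.40 to 74.4 ± 0.867 CPM (-2.44 ± 0.03), Col6a1 (-2.26 ± 0.06) and Itgbl1 (-2.17 ± 0.13).

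Markers of oligodendrocytes and vessels were higher in snap-frozen than fresh hippocampus beside these regional shifts. All 16 oligodendrocyte markers rose (median 0.68, adjusted p = 7.1e-20), Mag by 0.90 ± 0.02. So did all 16 endothelial markers (median 1.10, adjusted p = 9.1e-14), Flt1 by 1.43 ± 0.05. Of 13 markers of pericytes and smooth muscle 12 rose, with 1 falling when adjusted over the list alone (median 0.93, adjusted p = 0.000221). Adjusted p with an estimated correlation were 0.00428, 0.00171 and 0.0234. Meningeal markers ranked higher (11 of 14 rose, 2 fell, median 0.95, adjusted p = 0.00954, and 0.0636 with an estimated correlation), as did astrocyte markers (12 of 16 rose, 3 fell, median 0.35, adjusted p = 0.00105, and 0.118 with an estimated correlation). Osmotic stress genes ranked higher as well (8 of 14 rose, 2 fell, median 0.36, adjusted p = 0.00767, and 0.0613 with an estimated correlation). Within the astrocyte list Agt, which is abundant in thalamic astrocytes, rose by 1.78 ± 0.04, while Slc1a2 (-0.47 ± 0.02) and Slc1a3 (-0.55 ± 0.02) fell. Other glial lists did not pass: 11 of 17 microglial markers fell and 0 rose (median -0.25, adjusted p = 0.261), and of 13 markers of oligodendrocyte precursors 6 rose and 1 fell, or 7 and 3 adjusted over the list alone (median 0.19, 0.15).

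Of 27 postsynaptic scaffolds 24 fell and 1 rose in snap-frozen hippocampus (median -0.78, adjusted p = 7.4e-45, and 0.000202 with an estimated correlation), Agap2 by 1.06 ± 0.02. Markers of excitatory neurons (13 of 15 fell, median -0.90) and of hippocampal fields (14 of 15 fell, median -0.90) were lower by about as much, and the scaffolds were not separated from them. Immediate early genes fell (21 of 32, or 23 adjusted over the list alone, with 6 or 7 rising, median -0.35, adjusted p = 0.000231, and 0.0238 with an estimated correlation), Nr4a2 by 1.46 ± 0.05 and Jun by 0.99 ± 0.03. Synaptic vesicle genes ranked lower (12 of 45 rose and 29 fell, or 30 adjusted over the list alone, median -0.29, adjusted p = 0.00767, and 0.24 with an estimated correlation), Sv2b falling by 1.36 ± 0.02 while Syt2 (3.12 ± 0.04) and Vamp1 (2.07 ± 0.02) rose. Glycolytic enzymes ranked lower (3 of 17 rose, 12 fell, median -0.08, adjusted p = 0.0308, and 0.238 with an estimated correlation). The other 23 lists did not pass, solute carriers among them (128 of 280 rose and 65 fell, or 133 and 66 adjusted over the list alone, median 0.13, adjusted p = 0.105); with an estimated correlation that list passed (0.034). Signs of median, mean and camera direction differed for 8 lists, 0 of which passed, for example ionotropic receptors (median 0.20, mean 0.57, camera downwards). In all, 1231 genes changed by over 1 on the log2 scale, 935 upwards and 296 downwards, and 9036 passed at any size (4578 rose, 4458 fell, median absolute log2 change 0.37; 6784 and 2867 with library totals, which shift the median of all genes by 0.12). Libraries did not overlap for 65.2% of genes, against 10% by chance, and an assumed variation of 10% or 20% left 4953 or 2181 genes.

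In cortex, snap freezing was associated with smaller differences. Arc went from 136 ± 2.21 CPM in fresh to 41.7 ± 1.94 in snap-frozen cortex (-1.71 ± 0.04, adjusted p = 5e-23), and 18 of 32 immediate early genes fell (19 adjusted over the list alone), with 2 rising (3 adjusted over the list alone; median -0.28, adjusted p = 5.7e-21). All 14 choroid plexus markers fell (median -0.91, adjusted p = 6.4e-13), Ttr to 116 ± 3.11 CPM (-1.51 ± 0.06), as did 9 of 14 meningeal markers, 10 adjusted over the list alone, with 1 rising (median -0.39, adjusted p = 4.1e-07). Markers of the dentate gyrus and hippocampal fields rose in 10 of 14 and fell in 1 (median 0.72, adjusted p = 5.7e-10), C1ql2 by 1.92 ± 0.15 and Prox1 by 0.68 ± 0.08, and 13 of 15 striatal markers fell (median -0.33, adjusted p = 1.6e-12), Rgs9 by 0.46 ± 0.04. These 5 lists kept adjusted p of 0.00112, 0.0236, 0.0236, 0.039 and 0.00631 with an estimated correlation. Whether fresh and snap-frozen cortex samples held unlike shares of neighbouring regions by dissection was not tested.

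Another 12 lists passed in this comparison with the preset correlation and not with an estimated one (adjusted p from 0.126 to 0.414). Respiratory chain genes (55 of 79 rose, 62 adjusted over the list alone, median 0.15, adjusted p = 3e-14), ribosomal proteins (59 of 83, or 63, median 0.14, 1.2e-11) and proteasome subunits (30 of 37, median 0.18, 5.9e-12) rose without any member falling; with an estimated correlation their adjusted p were 0.307, 0.381 and 0.261. Glycolytic enzymes (9 of 17 rose, or 11 adjusted over the list alone, 1 fell, 0.261 with an estimated correlation) and the cytoskeleton (15 of 30 rose, 3 fell, 0.261) ranked higher. The same was seen for microglial markers (6 of 17 rose, 0.242), excitatory markers (5 of 15 rose, or 6 adjusted over the list alone, 3 fell, 0.35) and endothelial markers (5 of 16 rose, 0.414). Postsynaptic scaffolds ranked lower (20 of 27 fell, 21 adjusted over the list alone, 2 rose, median -0.18, 0.261 with an estimated correlation), and ion channels too (42 of 143 fell and 12 rose, 13 adjusted over the list alone, 0.381). Lower ranks were also found for astrocyte markers (12 of 16 fell, 1 rose, median -0.18, 0.126) and blood markers (5 of 7 fell, 1 rose, median -0.54, 0.261). With GC and length offsets the calls of ion channels (0.212), ribosomal proteins (0.332), microglial (0.0519) and endothelial markers (0.0607) were lost, and single libraries decided those of endothelial markers (0.153 without snap_frozen replicate 3, 0.0518 without fresh replicate 2) and excitatory markers (0.0561 without snap_frozen replicate 1). Of the other 20 lists, 4 differed in sign between median, mean and camera direction.

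Apart from these, the largest rises in snap-frozen cortex were of Xlr3b, which shares reads with a similar gene (1.87 ± 0.17), Il16 (1.64 ± 0.18), Tspan18 (1.60 ± 0.16) and Ndn, at 271 ± 1.62 against 93.6 ± 2.37 CPM (1.53 ± 0.03). The largest falls were of Plekhg4 (-1.61 ± 0.15), Egr2 (-1.27 ± 0.12) and Dok3 (-1.26 ± 0.09). In all, 102 of 14470 genes changed by over 1, 34 upwards and 68 downwards, and 4916 passed at any size (2376 rose, 2540 fell, median absolute log2 change 0.22; 2055 and 2822 with RLE factors, 1732 and 2238 with GC and length offsets, and 1440 and 2114 with DESeq2). Libraries did not overlap for 43.9% of genes, against 10% by chance. An assumed variation of 10% left 421 genes and one of 20% left 46.

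The direct comparison of vitrified with snap-frozen tissue held both changes. In hippocampus it therefore also carried the regional shifts of the snap-frozen samples, and a difference may come from either state. In hippocampus, all 16 astrocyte markers were lower in vitrified tissue (median -1.65, adjusted p = 3.3e-66), with Aqp4 at -2.41 ± 0.03, as were all 16 oligodendrocyte markers (median -0.996, adjusted p = 1.4e-25) and 13 of 14 thalamic markers (median -1.21, adjusted p = 6.9e-17). All 15 markers of the dentate gyrus and hippocampal fields (median 0.99, adjusted p = 1.5e-11), 13 of 15 excitatory markers, 2 falling (median 0.96, adjusted p = 2.8e-16), and 22 of 27 postsynaptic scaffolds, 1 falling (median 0.55, adjusted p = 2.8e-16), were higher. These kept adjusted p of 0.000692, 0.00282, 0.00282, 0.00383, 0.00134 and 0.00134 with an estimated correlation. Solute carriers passed here (78 of 280 rose, or 80 adjusted over the list alone, and 139 fell, median -0.15, adjusted p = 0.0394, and 0.0255 with an estimated correlation); Slc17a6 fell by 4.41 ± 0.05 and Slc6a11, a GABA transporter of astrocytes, by 3.02 ± 0.03, while Slc17a7 rose by 1.27 ± 0.02. Also lower were ependymal markers (12 of 12, adjusted p = 0.0169, and 0.0696 with an estimated correlation), microglial markers (14 of 17, 0.0351 and 0.104), endothelial markers (15 of 16, 0.0237 and 0.0849) and markers of pericytes (10 of 13, 0.00531 and 0.0438). Endothelial markers had risen against fresh hippocampus in both states, and more after snap freezing, so their place here does not mean a fall on vitrification. Markers of oligodendrocyte precursors (10 of 13, 0.00941 and 0.0547) and of striatum (8 of 14, 1 higher, 1.8e-05 and 0.0255) were lower as well. Lower functions were oxidative stress (13 of 17, 0.000724 and 0.0255), osmotic stress (8 of 14, 5 higher, 0.000806 and 0.0259), cholesterol synthesis (18 of 23, 1 higher, 0.00643 and 0.0438) and the unfolded protein response (16 of 20, 1 higher, 0.0351 and 0.127). Immediate early genes (18 of 32 rose, 6 fell, 0.0043 and 0.0438), synaptic vesicle genes (29 of 45 rose, 14 fell, 0.00173 and 0.135) and blood markers (6 of 7 rose, 1 fell, 0.000159 and 0.0255) were higher. With GC and length offsets the unfolded protein response and microglial lists stood at 0.0547. Of all 37 lists, 20 passed, 6 upwards and 14 downwards, and 14 did so with an estimated correlation. Median, mean and camera direction differed in sign for 5 lists, 0 of which passed.

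The largest rises in vitrified over snap-frozen hippocampus were of Ntn5 (3.57 ± 0.19) and Sec1 (2.91 ± 0.18), whose annotated spans overlap on opposite strands so that reads of one may have been counted for the other, Glp2r (3.46 ± 0.25), Krt2 (3.34 ± 0.16) and Col6a1 (2.76 ± 0.06). Barhl1 was at least 269-fold lower, Pou4f2 at least 250.6-fold, Pax7 at least 191-fold and En1 at least 169-fold lower in vitrified tissue, where they had 0 counts, and Shox2 had 1 count there, a ratio of 2012 (361 to 79511). In all, 1600 genes differed by over 1, 374 upwards and 1226 downwards, and 9849 at any size (4916 rose, 4933 fell, median absolute log2 change 0.41). With library totals, which shift the median of all genes by -0.06, 3980 rose and 5899 fell. Libraries did not overlap for 69.9% of genes, against 10% by chance, and an assumed variation of 10% or 20% left 6048 or 2826.

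In cortex, vitrified tissue was lower than snap-frozen tissue in all 16 astrocyte markers (median -0.64, adjusted p = 2.5e-42), Gfap by 1.58 ± 0.04, and all 14 choroid plexus markers (median -2.06, adjusted p = 1.1e-12), Ttr by 6.48 ± 0.14. Also lower were 12 of 14 meningeal markers (median -0.64, adjusted p = 3.7e-05) and 14 of 17 oxidative stress genes (median -0.20, adjusted p = 0.000212). Adjusted p with an estimated correlation were 0.0065, 0.0439, 0.0473 and 0.0473, and 15 further lists passed with the preset correlation alone. Of these, the respiratory chain had 65 of 79 members lower (median -0.20, adjusted p = 1.8e-09, and 0.427 with an estimated correlation) and blood markers 5 of 7 higher and 1 lower (median 0.91, adjusted p = 0.000107, and 0.107 with an estimated correlation). Ribosomal proteins (51 of 83 lower, 54 adjusted over the list alone, 9.9e-06, and 0.613 with an estimated correlation), proteasome subunits (25 of 37 lower, or 26, 1 higher, 0.000922 and 0.511) and the unfolded protein response (13 of 20 lower, or 14, 1 higher, 2.9e-05 and 0.0741) were among them. So were microglial markers (14 of 17 lower, 0.000402 and 0.107), hippocampal markers (11 of 14 lower, 1 higher, 0.000355 and 0.137), striatal markers (9 of 15 higher, 1 lower, 0.00116 and 0.0741), glycolysis (9 of 17 lower, 1 higher, 0.00196 and 0.274) and the cytoskeleton (15 of 30 lower, 5 higher, 0.00304 and 0.199). The remaining ones were cholesterol synthesis (11 of 24 lower, or 12, 2 higher, 0.0206 and 0.151), heat shock (13 of 21 lower, 2 higher, 0.00304 and 0.121), histones (6 of 9 lower, or 8, 0.00243 and 0.0741), endothelial markers (8 of 16 higher, 0.0135 and 0.427) and ion channels (56 of 143 higher, 30 lower, or 57 and 31, 0.0222 and 0.511). GC and length offsets removed the calls of ion channels (0.350), ribosomal proteins (0.211) and proteasome subunits (0.132), and without snap_frozen replicate 3 the ion channels stood at 0.0513. Signs of median, mean and camera direction differed for 6 lists, 0 of which passed. The largest rises were of Col24a1 (2.38 ± 0.11), Col5a1 (2.12 ± 0.06), Col6a4 (1.97 ± 0.14), Snhg11, at 2670 ± 47.8 against 713 ± 34.1 CPM (1.90 ± 0.03), and Ybx2 (1.74 ± 0.15). After Ttr, Mrc1 (-2.55 ± 0.21), Kl (-1.92 ± 0.14), Itih2 (-1.90 ± 0.19) and Myoc (-1.67 ± 0.07) fell furthest. In all, 410 genes differed by over 1, 286 upwards and 124 downwards, and 7183 at any size (3687 rose, 3496 fell, median absolute log2 change 0.28; 3365 and 3647 with GC and length offsets, and 3360 and 4088 without a filter). Libraries did not overlap for 54.6% of genes, against 10% by chance, and an assumed variation of 10% or 20% left 2515 or 551.

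**Figure D3:**
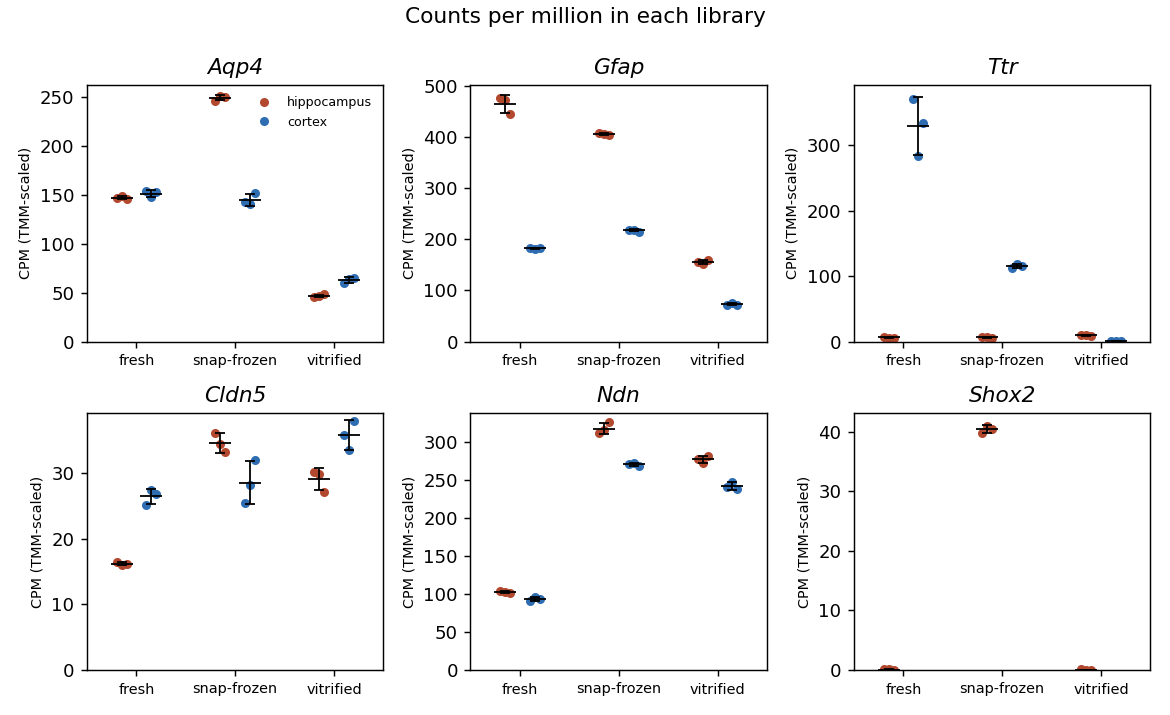
CPM, scaled by TMM factors, of Aqp4, Gfap, Ttr, Cldn5, Ndn and Shox2 in each library of hippocampus (red) and cortex (blue). Bars are means ± SD of 3 libraries. Shox2 was not among the tested genes of cortex and has no points there.

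Genes that changed alike after both treatments were counted against the shared fresh libraries. In hippocampus 2840 genes moved the same way, 1320 upwards and 1520 downwards, and 129 of them by over 1 in both; 2119 moved in opposite directions. Ndn rose (1.43 in vitrified and 1.63 in snap-frozen tissue), while Shank3 (-0.97 and -0.97), Ppp1r9b (-0.77 and -0.83), Ddn (-0.63 and -1.03), which act at dendritic spines, and the calcium channel Itpr1 (-0.74 and -0.84) fell. In cortex 1531 genes moved the same way, 609 upwards and 922 downwards, and 22 by over 1; 982 moved in opposite directions. Ndn rose (1.37 and 1.53), and Arc (-1.57 and -1.71), Ttr (-7.99 and -1.51), Igf2 (-1.13 and -0.61) and the insulin-degrading enzyme Ide (-0.78 and -0.62) fell. Simulated unchanged groups shared 0.45 genes on average in hippocampus and 0.15 in cortex, at most 2, and independent lists would share 2218 and 990. The covariance of fold changes was 0.0217 in hippocampus against 0.0077 simulated, a difference of 0.0139, and 0.0198 in cortex against 0.0080, a difference of 0.0118. Pearson r across genes was 0.075 and 0.21, against 0.49 simulated in both tissues. In groups without any change hardly any gene can pass, and the shared controls alone set the simulated r. The simulated counts and r therefore do not measure how alike the treatments were. Groups that change independently of each other against the same fresh libraries were not simulated. The 3 fresh libraries of a tissue are too few to split, so part of the excess may come from the shared controls.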

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

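Changes that differed between hippocampus and cortex are described here as cortex minus hippocampus on the log2 scale. The tests of the second region list, of thalamic markers in cortex and of astrocyte markers against snap-frozen tissue were chosen only after the result was seen. The offsets for GC content and length were fixed before the data were examined, and the second astrocyte list before its own result was seen.

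Between fresh and vitrified samples, the change of choroid plexus and meningeal markers was lower in cortex than in hippocampus, where 5 of 11 choroid plexus markers fell too (median -0.41). In cortex, Ttr was at 330 CPM in fresh, 116 in snap-frozen and 1.29 in vitrified samples. Unlike amounts of choroid plexus and meninges in the dissected cortex samples were not tested and stay open. Ttr rose by 0.57 in hippocampus and fell by 8.01 in cortex, a difference of -8.58, and the choroid plexus potassium channel Kcnj13 (1.41 and -3.11) differed by -4.53. The meningeal proteoglycan Fmod (1.42 and -1.32) differed by -2.75, Prg4 (0.71 and -1.76) by -2.47, and Kl, a coreceptor of the choroid plexus (-0.04 and -2.53), by -2.49. In the other direction stood the forebrain transcription factor Six3 (2.63, from -2.99 and -0.35), Frmd7 (1.54, from 0.20 and 1.74), LOC100861978, which shares reads (1.52), the neuropeptide Trh (1.45) and the ciliary gene Ccdc153 (1.26). Some of these rested on few libraries or on the method: adjusted p was 0.0813 for Six3 without hippocampus vitrified replicate 1, 0.295 for Trh without hippocampus fresh replicate 2, 0.229 for Ccdc153 without cortex vitrified replicate 1 and 0.194 for LOC100861978 with DESeq2. In all, 1913 of 14827 genes differed between tissues, 1040 higher and 873 lower in cortex, of which 216 by over 1; in the joint fit 4203 genes passed in the same direction in both tissues and 163 in opposite ones. Of 40 assignments that exchange the states of libraries, the real one included, 7 gave a count at least as large, the highest other being 4044. Each other assignment with a count above 0 kept or wholly exchanged the states of 1 tissue, which turns that tissue's own change into a difference between the tissues. These assignments therefore do not test chance, for this count or for that of snap freezing. In simulated data the same test made 10 false calls on vitrification and 18 on snap freezing. Changes were planted there in cortex alone, so false calls among changes shared by both tissues were not measured.

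Some lists changed unlike in the tissues between fresh and vitrified samples. Lower in cortex were those of choroid plexus (-2.30), meningeal fibroblasts (-1.43), blood cells (-0.58), endothelial cells (-0.43) and immediate early genes (-0.42). Higher in cortex were those of microglia (0.44), astrocytes (0.39), ependymal cells (0.37), oligodendrocytes (0.32), oligodendrocyte precursors (0.17), cholesterol synthesis (0.12) and inhibitory neurons (0.044). With an estimated correlation the calls of inhibitory neurons (adjusted p = 0.127) and ependymal cells (0.124) were lost. Postsynaptic scaffolds did not pass (0.01, adjusted p = 0.993). Of the 11 fixed genes that could be tested, Ttr, Fos (-0.50), Cldn5 (-0.45) and Aqp4 (0.34) differed.

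The differences between snap-frozen and fresh samples were unlike in the tissues. The largest differences below 0 included 4 transcription factors that rose in hippocampus and were near 0 counts or did not pass in cortex. They were -10.44 for Tfap2d, -10.33 for Barhl1, -8.83 for Shox2 and -8.18 for Tfap2b, fitted values that depend on the prior count where a group is near 0, and -6.78 for the Wnt antagonist Sfrp5 (6.28 in hippocampus and -0.50 in cortex). Barhl1 did not pass without cortex fresh replicate 2 (adjusted p = 0.9998). The deiodinase Dio3 (4.58), the exchanger Slc9a4 (4.23, from -2.17 and 2.07), the desmosomal Dsp (3.41, from -0.57 and 2.85), Krt2 (3.40) and Spink8, a gene of pyramidal neurons of hippocampus (3.07, from -1.30 and 1.77), stood higher in cortex. In all, 8152 genes differed, 3950 higher and 4202 lower in cortex, of which 1550 by over 1, and 1 of 40 assignments, the real one, reached that count, the highest other being 6170, with the same limit. Across genes the log2 changes of the tissues had a Pearson r of -0.08.

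Among lists, the change from fresh to snap-frozen samples was lower in cortex than in hippocampus for markers of meningeal fibroblasts (-1.56), choroid plexus (-1.46), thalamus (-1.18), endothelial cells (-0.995), pericytes (-0.98), striatum (-0.86), oligodendrocytes (-0.67), astrocytes (-0.57) and oligodendrocyte precursors (-0.30), and for osmotic stress genes (-0.58). For thalamus (medians of 1.28 in hippocampus and -0.06 in cortex), endothelial cells (1.09 and 0.08) and pericytes (0.92 and 0.01) it was hippocampus that moved. The medians of meningeal fibroblasts (0.94 and -0.42) and choroid plexus (0.39 and -0.93) had opposite signs in the tissues. In the test of hippocampus alone, choroid plexus markers did not pass and meningeal markers passed only with the preset correlation. The change was higher in cortex for markers of dentate gyrus and hippocampal fields (1.27), excitatory neurons (1.02) and microglia (0.37), for postsynaptic scaffolds (0.57), synaptic vesicle genes (0.26), proteasome (0.25), glycolysis (0.22), the respiratory chain (0.17) and ribosomal proteins (0.12). With an estimated correlation adjusted p was 0.562 for synaptic vesicle genes, 0.791 for the respiratory chain and for ribosomal proteins, 0.557 for the proteasome, 0.108 for glycolysis, 0.104 for oligodendrocyte precursors and 0.06 for microglia and for choroid plexus.

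Thalamic markers were higher and hippocampal markers lower in snap-frozen hippocampus, and if neighbouring regions were in these samples, other genes of those regions would rise: of 25 genes of a second region list 15 could be tested, of which 12 rose and 1 fell (median 4.62 without the genes too low to test, or 4.48 with the gene at 0 to 3 counts at its bound). Over the 23 genes listed, tested or not, 16 had more counts in snap-frozen than fresh hippocampus and 5 fewer, 5962 against 2042 in sum, which is consistent with that origin; in cortex 11 had more and 11 fewer. Offsets for GC content and length left the thalamic median at 1.30, which excluded that origin. A freezing effect common to both tissues would show in cortex, where the thalamic median was -0.030. This argues against such an effect, as far as the snap-frozen cortex samples serve as a reference. A dissection that differed between the states would give both more thalamic and fewer hippocampal transcripts, and the labels do not describe it.

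For astrocyte markers, lower in vitrified tissue, a smaller share of astrocyte RNA would lower astrocyte genes outside the list: in a second list, 15 of 15 fell in both tissues (median -1.11 in hippocampus and -0.64 in cortex), in line with that origin. GC and length offsets left the median of the first list at -0.88 or lower, which excluded that origin. Fresh samples holding more astrocyte RNA by dissection would leave no fall against snap-frozen tissue, where the medians were -1.65 in hippocampus and -0.64 in cortex. The cortex value argues against such a dissection, as far as the snap-frozen samples serve as a reference. Snap-frozen hippocampus was itself higher than fresh in thalamic and astrocyte markers, so the value there cannot decide. A dissection of the vitrified samples that differed was not tested and stays open. Loss of the cells, loss of RNA from them and lower transcription would all give this pattern and were not separated.

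Assignments of libraries to exchanged groups were drawn for each comparison, 10 of each including the real one. The real counts of 7135, 9036 and 9849 genes in hippocampus and 5855, 4916 and 7183 in cortex were each reached by 1 of 10, the highest other being 0 genes. That is too few for a share under 0.05.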

How the results depend on the processing

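All alternatives were fixed before the data were examined, except that fits with an assumed variation of 10% or 20% were tests chosen only after the data were seen. Among the named genes, the examples of lists and the lists themselves, no call was reversed by any alternative applied to it. Calls of the other genes were not compared one by one. Library totals shift the median of all genes by 0.12 in snap_frozen against fresh hippocampus, so signs of small changes may depend on the scaling. The balance of rises and falls turned with some alternatives in every comparison but snap_frozen against fresh cortex: to 4806 and 2835 with library totals in vitrified against fresh hippocampus, from 3353 and 2502 to 3048 and 3135 with GC and length offsets in vitrified against fresh cortex, and from 3687 and 3496 to 3360 and 4088 without a filter on low counts in vitrified against snap_frozen cortex. Counts fell where more variation was assumed, as the test then needs larger differences: 2481 and 673 genes for vitrified against fresh hippocampus at 10% and 20%, 4953 and 2181 for snap_frozen against fresh, 6048 and 2826 for vitrified against snap_frozen, and 1929 and 283, 421 and 46, and 2515 and 551 in cortex. They also fell where a log2 change over 1 was asked for, which was met by 550, 1231 and 1600 genes in hippocampus and 260, 102 and 410 in cortex. DESeq2 gave lower counts in every comparison too, 5577, 7742 and 8629 genes in hippocampus and 4507, 3554 and 5907 in cortex. With an estimated correlation 9 lists passed for vitrified against fresh hippocampus, and in cortex 6, 5 for snap_frozen against fresh and 4 for vitrified against snap_frozen; with fry, which tests a list by itself, 32, 31 and 36 passed in hippocampus and 22 for vitrified against fresh cortex. Without single libraries the gene counts were 6403 to 7150, 8542 to 9076 and 9404 to 9952 in hippocampus, and 5032 to 6609, 3841 to 4793 and 6327 to 7072 in cortex. The list counts without single libraries were 14 to 16, 14 to 14, 20 to 21, 12 to 13, 17 to 18 and 19 to 20, and the genes differing between tissues 1582 to 1651 on vitrification and 7714 to 8068 on snap freezing. No pairing of samples by replicate number was seen: the correlations of libraries with the same number were -0.054 to 0.041 in hippocampus and -0.051 to 0.076 in cortex. With replicates so alike, these values cannot exclude it. With a replicate block the counts were 7075, 9000 and 9842 genes in hippocampus, 5863, 4947 and 7198 in cortex, and 14 and 14 lists for both hippocampal comparisons with fresh tissue; with block and GC offsets, 7110, 9028 and 9897 in hippocampus. The block moved the oligodendrocyte precursor list of vitrified hippocampus to 0.0502, and brought the inhibitory (0.0418) and precursor lists (0.0481) of snap-frozen cortex past the test. Among fixed genes, Slc17a7 passed with GC and length offsets (0.0118 in hippocampus, 0.0463 in cortex), and Hspa1a in hippocampus with library totals (0.0123) and without fresh replicate 1 (0.0313). The osmotic list of vitrified hippocampus passed with the filter at 1 CPM (0.0417). Merging of duplicate libraries was planned and not run. The cause of these shifts was not tested.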

Other observations

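The tests of the Fgfbp3 gene beside Ide and of dendritic genes were written before their own results were seen. Single genes of the next sentences were chosen after their values were seen. Ndn rose in all 4 comparisons with fresh tissue, to 278 ± 4.52 CPM (n = 3) in vitrified and 318 ± 7.64 in snap-frozen hippocampus from 103 ± 1.44 in fresh. Snhg11 rose on vitrification and fell on snap freezing in cortex (1.00 ± 0.03 and -0.90 ± 0.03). Sox17 was at 10.4 CPM in both vitrified and snap-frozen hippocampus, and Klf2 rose in both (1.50 ± 0.11 and 1.13 ± 0.11), so these endothelial genes were lowest in fresh tissue. Heph fell on vitrification (-2.50 ± 0.14) and rose on snap freezing in hippocampus (0.69 ± 0.08).

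Ide was lower in every state than in fresh tissue: by 0.84 ± 0.04 in vitrified and 0.60 in snap-frozen hippocampus, and by 0.78 and 0.62 in cortex. The chromosomal segment of Ide and Fgfbp3 is known to be duplicated in part of C57BL/6J mice, and the labels give no strain. If fresh samples carried more copies, Fgfbp3 would fall alike. It fell by 0.33 ± 0.11 and 0.33 in hippocampus and by 0.43 and 0.39 in cortex, a median of -0.36, in line with a copy difference but close to the bound of -0.3 set for it. Between vitrified and snap-frozen tissue Fgfbp3 hardly differed (-0.01 and -0.04), and Ide fell by 0.24 and 0.16. Genes beside the segment moved both ways and decide nothing: of 5 in vitrified hippocampus 2 fell (-0.75 ± 0.20 and -0.27 ± 0.04) and 1 rose (0.15 ± 0.04), 0 passed in vitrified cortex, and after snap freezing 1 rose in each tissue while 2 fell in hippocampus and 1 in cortex, Btaf1 in both (-0.55 and -0.49).

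Spine and dendritic genes were tested as a sign of lost dendrites in vitrified tissue. Of 11 in vitrified hippocampus 9 fell and 1 rose against fresh (median -0.19). In vitrified cortex 5 fell and 3 rose (median -0.043, quartiles of -0.18 to 0.06). By the rule written beforehand, which used the median alone, the cortex value counted against lost dendrites. A further condition, not in that rule, asked that the lower quartile clear the same bound, which it did not. Members went both ways in cortex, and the question was left undecided. In snap-frozen tissue 10 of 11 fell and 0 rose in both tissues (medians of -0.44 in hippocampus and -0.15 in cortex, the latter -0.07 with GC and length offsets). Markers of excitatory neurons and hippocampal fields fell too in snap-frozen hippocampus, and the dendritic genes were not separated from them. Whether vitrification and snap freezing share a fall of dendritic genes therefore stays open.

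The counter, its strand setting and the annotation behind the values would settle genes that overlap, such as Ntn5 and Sec1, and the animals behind the libraries would settle what the p-values measure.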
